A study of Mus musculus with 8 samples.

How the data were processed

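RNA of mouse TEC100.4 cells with a doxycycline-inducible mutant of TFII-I, β or δ isoform, was hybridised to one-colour Agilent mouse expression arrays. Per the labels, cells were cultured for 24 h with or without doxycycline, and 200 ng of total RNA from a column kit was labelled with Cy3 by a low input amplification kit. The scanner images were quantified by the authors with Agilent Feature Extraction 11.5.1.1, per the file headers, and the deposited values are linear spot intensity values, background-subtracted and spatially detrended by that software, with no normalization between arrays. The recorded size of its multiplicative detrending fit (root mean square) was 0 on the treated β replicate 2 and both treated δ arrays. It was 0.081 on the treated β replicate 1 and between 0.067 and 0.126 on the untreated arrays. This step was therefore uneven between treated and untreated arrays. The deposited flags for spots well above background, saturated or outlying are those of the same software. The untreated samples' genotype label names the wild type protein while their titles name the mutant line without doxycycline; groups were taken from the titles. The study's own statistical test is not given in the sources used here.

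Samples were grouped by line and treatment into 4 groups of 2 arrays, and replicate numbers only name the arrays. Replicates were compared before use: the correlation between arrays of a group across genes was between 0.993 and 0.997 without the probes in a local defect, no pair was identical, and the median absolute deviation of their difference, scaled to an SD, lay between 0.119 and 0.254 on the log2 scale.

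The log2 of the processed intensity was averaged over the spots of a probe, leaving out control spots and spots flagged as outliers, and each array's 75th percentile was subtracted. Of 56605 probes, 98 had no unflagged spot on some array and were left out. Names came from a RefSeq gene table of assembly GRCm38.p6, matched on the probe's transcript accession without its version, with no coordinates printed because the file headers name another build. It named 32931 probes, and 23576 without a match were not tested among genes. Probes were kept where well above background on both arrays of at least 1 group (27215), and each gene was represented by its brightest probe, which left 19023 genes. No probe was saturated. Of the 13 called genes of the β line with several kept probes, 3 had probes of opposite sign, and none of 2 in the δ line.

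All 8 arrays were fitted with 1 mean per group in limma 3.58.1 (R 4.3.3, lmFit and eBayes), with 4 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over all genes tested with a threshold of 0.05. The contrasts were doxycycline against none in each line, their mean, their difference, and the δ line against the β line without and with doxycycline. Of 48 gene lists, the 46 with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over lists, again with the correlation estimated from the residuals, and with fry, which tests whether a list's genes move one way on balance. Fry gave an unadjusted p under 0.05 for 13 lists in the β line, 5 in the δ line and 2 for the difference. No probe named a mitochondrially encoded gene, so that list was not measured.

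For a gene not well above background on every array of a group, the fold is a bound: the mean of the brighter group against the mean, over the arrays of the dimmer group, of the higher of the lowest signal among probes well above background and the probe's own signal.

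The rule for named genes was fixed before the data were examined. For doxycycline in each line it takes Gtf2i and its family and up to 8 rises and 8 falls, the largest by log2 fold change among genes past the threshold that were well above background on all 4 arrays compared and whose groups do not overlap, without names that only number a locus. To these it adds up to 2 bounds per direction and, from each list that passes, up to 3 members per direction with the smallest p. For the other contrasts it takes up to 5 per direction and, between lines, bounds as above. The text departs from this rule for list members: it names those that go the way of their list, a narrowing made after the values were seen. Of the members that go the other way, 0 passed by limma when adjusted over the list alone in the 11 lists of the β line and the 4 of the δ line. Gtf2i between the untreated lines and 10 genes of the closing observations were chosen after their values were seen. Some list members that the rule takes are not reported here.

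Tests were checked on simulated data of 18012 genes, the set without the patch described below, with 200 changed genes. Each gene had its real mean and independent normal noise of the spread fitted by eBayes. The reported fit holds 19023 genes and the patch, so these shares do not describe it directly. In the β comparison, 70.1% of genes changed by 2-fold and all 66 changed by 4-fold were recovered, but only 4 of 67 changed by 1.41-fold, with 4 false calls among 121. In the δ comparison these were 77.6%, all 66 and 4 of 67, with 7 false calls among 129.

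The alternatives tried were normexp background correction (offset 50), quantile normalization, median centring, no filter on dim probes, a filter on all arrays, the mean over probes, an intensity trend, fits of only the 4 arrays compared, the slide column as a block, and leaving out each array in turn. The files hold no mean spot signal, so normexp used the median spot signal and the median local background. Its offset is added to every signal, which shrinks folds against a dim group by construction. Normexp values under a bound therefore do not test that bound. All arrays share 1 slide and 1 scan session, so a slide or scan block was not applicable. Alternatives chosen after seeing the data concern the patch of deviant tiles. Both call a tile of 8 by 8 spots deviant where its spots with a median signal above 200 deviated at the median by over 0.3 on the log2 scale from their median over all arrays, a limit that was also set after seeing the data. The first left out such spots on the array concerned alone (19066 genes, of which 1537 then lacked 1 array). It was replaced, after its counts had been seen, because groups with a lone array carried some of its calls, by leaving out on all arrays every probe with such a spot (18012 genes). Counts under both are given in the closing section, and the report gives those of the second. Camera takes no missing values, so gene lists were not tested under the first.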

Results

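Gene expression was measured in TEC100.4 cells, an immortalized line of cortical thymic epithelial cells of the mouse, that carry a doxycycline-inducible mutant of TFII-I, the transcription factor encoded by Gtf2i. One line carried the β isoform of the mutant and the other line the δ isoform. Each line was grown for 24 h with or without doxycycline, which gave 4 groups of 2 one-colour arrays, 8 arrays in all. Nothing in the labels says that the arrays of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Between 39512 and 45080 probes per array were well above background, with 43345 or more on the arrays with doxycycline and 40698 or fewer on those without. The small number of arrays limits the precision. All arrays lay on 1 slide, with the doxycycline arrays in its first row and the untreated arrays in its second row, so row and treatment cannot be told apart. No treated line without a mutant was analysed here, so doxycycline and the induced protein are not separated either.

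One array stood apart. On the untreated δ array called replicate 1, 80 of 1008 tiles of 8 by 8 spots deviated at the median by over 0.3 on the log2 scale, against at most 1 such tile on any other array. Of these tiles 55 were darker, down to -7.83, and 25 were brighter, up to 0.72. Together they are called the patch below and held 7.65% of the spots that are not controls. The correlation with the other array of its group, across genes, was 0.965, and it was 0.993 without the probes in such tiles. The number of genes past the threshold in each comparison is therefore given a second time without the probes in deviant tiles, a choice made after seeing the data, which left 18012 genes in place of 19023.

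**Figure D1:**
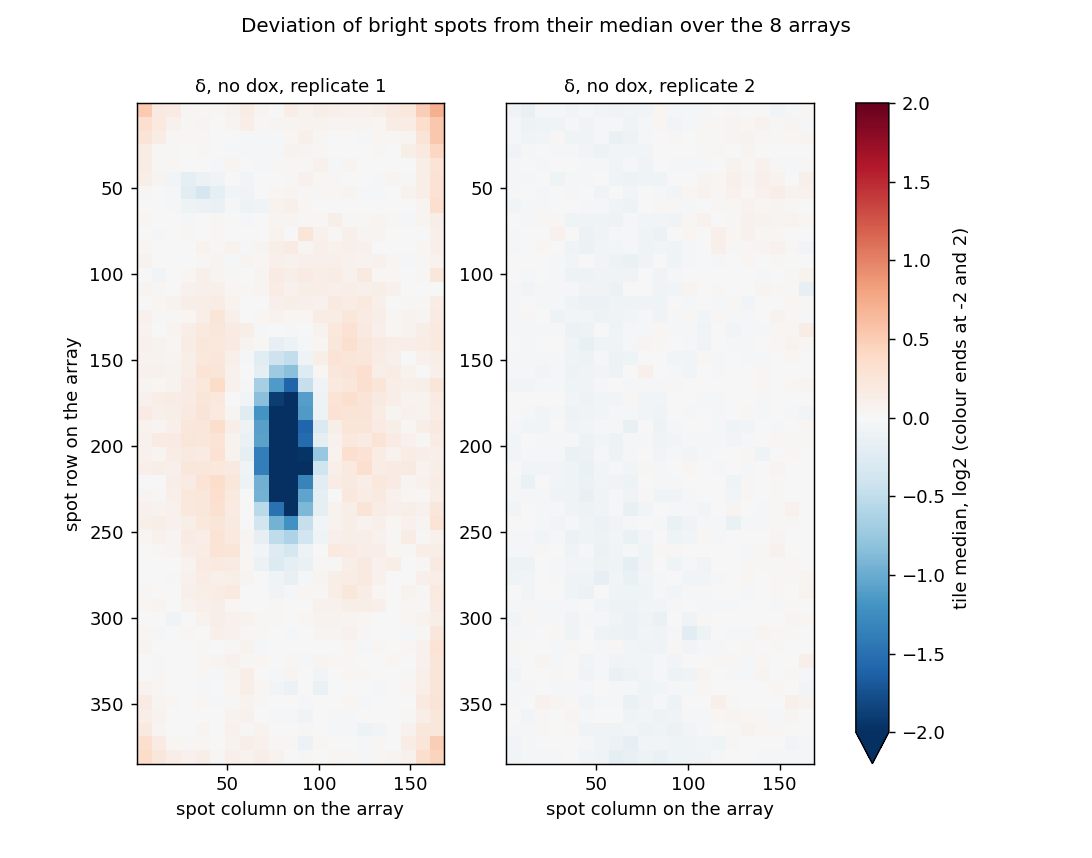
Median deviation of bright spots from their median over the 8 arrays, in tiles of 8 by 8 spots, for both untreated δ arrays. The axes are the spot's column and row on the array and the colour is the tile median on the log2 scale. Replicate 1 shows a dark patch that reaches -7.83, while no tile of replicate 2 lies below -0.22.

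The first comparison concerns Gtf2i, the gene whose mutant was to be induced. Its brightest probe, A_55_P2073467, read 4.51 ± 0.17 (SD, n = 2) without and 4.62 ± 0.05 with doxycycline in the β line, on the log2 scale relative to each array's 75th percentile. In the δ line it read 5.18 ± 0.15 and 5.27 ± 0.02. Neither difference passed the limma test, with a log2 fold change of 0.11 ± 0.12 (SE, adjusted p = 0.716) in the β line and 0.09 ± 0.12 (adjusted p = 0.725) in the δ line. With an untreated array left out the sign of this small difference turned, to -0.01 in the β line without its untreated replicate 1 and to -0.01 in the δ line without its untreated replicate 2. A dimmer probe of the gene, A_55_P2040907, read -2.34 ± 0.30 without and -1.03 ± 0.03 with doxycycline in the β line, where both treated arrays lay above both untreated arrays, and -1.80 ± 0.18 and -1.67 ± 0.19 in the δ line. Its difference in the β line was 1.31 ± 0.19 (SE, adjusted p = 0.10 over 45112 probes, unadjusted p = 0.000384). As a mean over its probes, Gtf2i had a log2 fold change of 0.52 in the β line (limma adjusted p = 0.0943). The brightest probe alone had a value of 0.06 there after normexp, and the dimmer probe was not examined after normexp. In the δ line the brightest probe had a value of 0.03 after quantile normalization and 0.14 without the patch. Which part of the transcript each probe covers, and whether it matches the mutant, is not known here. The related genes Gtf2ird1 and Gtf2ird2 had adjusted p-values of 0.526 or more at the level of single probes in both lines.

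**Figure D2:**
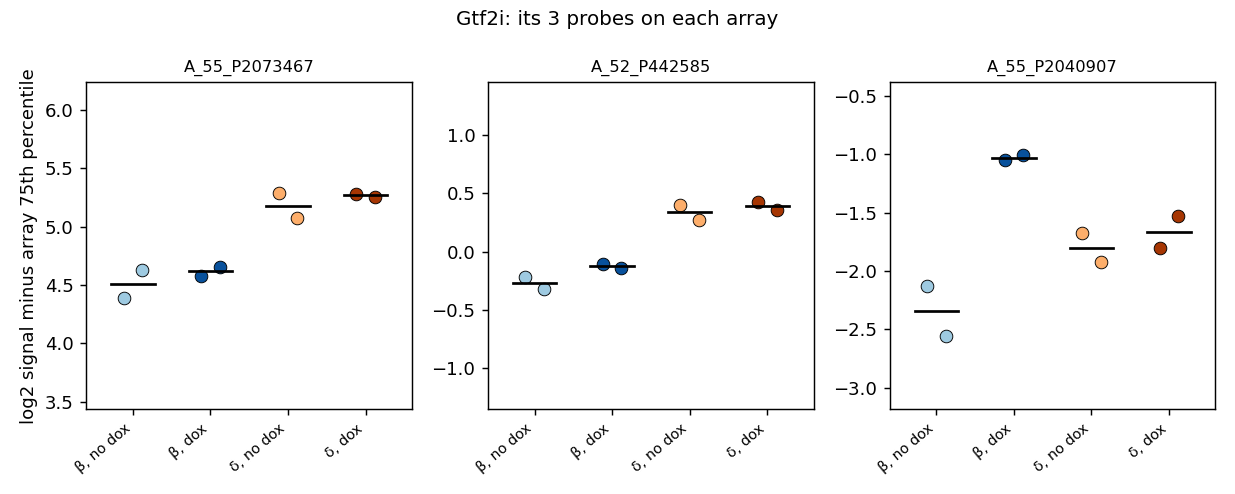
The signal of the 3 Gtf2i probes on each of the 8 arrays, as log2 signal minus the array's 75th percentile, with each group's mean as a line. All panels span the same range. The probe A_55_P2040907 lies near -1.03 on the β arrays with doxycycline and near -2.34 on those without.

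In the β line, Ccr7, a chemokine receptor, fell with doxycycline 4.25-fold (log2 fold change -2.09 ± 0.11 SE, n = 2 and 2, limma adjusted p = 0.0124). P2rx7, an ion channel opened by ATP, fell 3.95-fold (-1.98 ± 0.11, adjusted p = 0.0124) and Gpr182, a G protein-coupled receptor, fell 5.09-fold (-2.35 ± 0.21, adjusted p = 0.0377). Further falls were in the pannexin gene Panx3 (-1.68), Mmrn1 (-1.46), the neuromedin U receptor Nmur2 (-1.42), the meiotic gene Spo11 (-1.31) and the kinase gene Sbk3 (-1.29), with adjusted p between 0.036 and 0.0481. The largest rises were in the lipase-related gene Pnliprp2 (3.14-fold, 1.65 ± 0.17, adjusted p = 0.0405), the sodium pump subunit Atp1b2 (2.51-fold, 1.33 ± 0.10, adjusted p = 0.0299) and the zinc importer Slc39a4 (2.38-fold, 1.25 ± 0.12, adjusted p = 0.0377). Ppp1r1c (1.20), Gng13 (1.13), Olfr282 (1.07), the 7SK RNA gene Rn7sk (1.03) and H2-Bl (2.01-fold) rose as well, with adjusted p of 0.0405 or less. Cd209f and Ifitm1, which were not well above background on either untreated array, rose at least 2.40-fold (adjusted p = 0.0409) and at least 2.11-fold (adjusted p = 0.0289). Spots of Rn7sk and Nmur2 lay in the patch of the untreated δ array, which enters the spread of their test but not their difference. Of these 18 genes, none passed without the treated β replicate 2 or either treated δ array (adjusted p between 0.0666 and 0.228), and Ccr7, P2rx7 and Gpr182 alone passed without the treated β replicate 1. Without the untreated β replicate 1, 9 did not pass (Cd209f, Gng13, Gpr182, H2-Bl, Olfr282, Panx3, Pnliprp2, Rn7sk and Spo11, adjusted p up to 0.112), and without the untreated β replicate 2, 8 did not (Nmur2 and the former except Panx3 and Pnliprp2, up to 0.0818). Under other processing, 18 did not pass in a fit of the 4 arrays compared or with a replicate block, 16 without a filter on dim probes, 11 after normexp, 11 after median centring, 4 after quantile normalization and 3 as means over probes. Values moved by over 1.5 times for Ppp1r1c as a mean over probes (0.36, limma adjusted p = 0.545). After normexp they did so for Mmrn1 (-0.56), Spo11 (-0.51), Panx3 (-1.04), Pnliprp2 (1.004), Ifitm1 (0.69) and Cd209f (0.77). Those of Ifitm1 and Cd209f are under their bounds, but the normexp offset shrinks folds against dim groups by construction.

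In all, 47 of 19023 genes passed in the β line, 22 higher and 25 lower with doxycycline, and 296 of 18012 passed without the probes in the patch, 172 higher and 124 lower. The direction of the calls depended on scaling, with 46.8% of them higher as reported, 28.3% of 53 after quantile normalization, 28.6% of 14 after median centring and 23.1% of 13 after normexp background correction. Leaving out 1 array moved the count to 15 or 3 (β with doxycycline, replicates 1 and 2), 83 or 93 (β without), 0 for either δ array with doxycycline and 203 for either δ array without.

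Gene lists fixed before the data were examined showed a broader pattern in the β line, where 11 of 46 passed camera at the preset correlation and none with an estimated correlation between genes (lowest adjusted p = 0.745). Genes of cholesterol biosynthesis lay lower with doxycycline: 22 of 24 measured genes were below zero, the median was -0.23, and camera gave an adjusted p of 0.000144. No member of any of the 11 lists passed over all genes tested, while 5 genes of this list fell and 0 rose when adjusted over the list alone. Among these, Nsdhl and Fdps had log2 fold changes of -0.73 and -0.67. Genes of the G2/M phase and mitosis also lay lower, with 28 of 33 below zero (median -0.18, adjusted p = 0.000144), and 6 fell when adjusted over the list alone, among them Hmmr (-0.65), the mitotic kinase Aurkb (-0.70) and Cdk1 (-0.43). As a mean over its probes Hmmr had a value of 0.07. The list of MYC and ribosome biogenesis genes had 25 of 29 below zero (median -0.16, adjusted p = 0.000384), with 4 that fell when adjusted over the list alone. These included Gnl3 (-0.58), Nop16 (-0.47) and Dkc1 (-0.52, but 0.30 as a mean over its probes). With an estimated correlation these 3 lists had an adjusted p = 0.745. Cholesterol biosynthesis and G2/M passed with each array left out in turn, but without the untreated β replicate 2 the median of G2/M was -0.09, and the MYC list did not pass (median -0.03, adjusted p = 0.121). Without the untreated β replicate 1 the medians of cholesterol biosynthesis and of the MYC list were -0.35 and -0.27, and as means over probes that of G2/M was -0.11.

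Metabolic and protein turnover lists moved less. Glycolysis and lactate genes had 15 of 24 below zero (median -0.08, adjusted p = 0.0145), with 6 that fell when adjusted over the list alone, among them Hk2 (-0.72), Pfkfb4 (-0.69) and Tpi1 (-0.40). Glutamine and nucleotide synthesis had 19 of 26 below zero (median -0.10, adjusted p = 0.00974) and 7 that fell when adjusted over the list alone, such as Dhodh (-0.53), Gmps (-0.52) and Adss (-0.42). Both had an adjusted p = 0.745 with an estimated correlation. The unfolded protein response of the endoplasmic reticulum had 19 of 29 below zero (median -0.06, adjusted p = 0.0301), and 1 gene, Manf (-0.58), fell when adjusted over the list alone, beside values of -0.65 for Sec24d and -0.35 for Edem1. The proteasome had 22 of 30 below zero (median -0.08, adjusted p = 0.0382) with 0 passing over the list alone by limma and values of -0.38, -0.37 and -0.24 for Psmb7, Psmd11 and Psmd14. G1/S and DNA replication had 21 of 32 below zero (median -0.07, adjusted p = 0.0497) and 2 that fell when adjusted over the list alone, Slbp (-0.85) and Cdc45 (-0.45, but -0.14 as a mean over its probes), beside a value of -0.33 for Pole. The adjusted p with an estimated correlation was 0.772 for each of these. Without the untreated β replicate 2, the lists of this paragraph did not pass, with adjusted p between 0.121 and 0.746, and the medians of the proteasome and of G1/S turned to 0.02 and 0.03; without the treated β replicate 1, glycolysis alone of them passed. Glutamine and nucleotide synthesis alone of them passed both without a filter on dim probes and with probes well above background on all arrays. Without the untreated β replicate 2 the medians of glycolysis and of glutamine and nucleotide synthesis were -0.02 and -0.03. Without the treated β replicate 1 the medians of glycolysis and of the proteasome were -0.16 and -0.01, and without replicate 2 those of the proteasome and of G1/S were -0.14 and -0.03. Without the untreated β replicate 1 the medians were -0.17 for glutamine and nucleotide synthesis, -0.10 for the unfolded protein response, -0.19 for the proteasome and -0.16 for G1/S. Over all alternatives G1/S passed in 6 of 18. It did not pass without the treated δ replicate 2, without either untreated δ array, or without the probes in the patch (adjusted p = 0.0519, 0.0568, 0.0588 and 0.0525), nor after quantile normalization, in a fit of the 4 arrays compared or with a replicate block (0.0954, 0.0665 and 0.0772). After median centring neither G1/S nor the proteasome passed (medians -0.11 and -0.12, adjusted p = 0.0530). The median of glycolysis was -0.24 after quantile normalization, and that of the unfolded protein response was -0.11 after it, -0.10 after median centring and -0.02 without the patch.

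A further 3 lists were shifted upward in the β line. Replication-dependent histones, transcribed mostly in S phase, are encoded by many near-identical copies that a probe may not tell apart. Their list had 12 of 13 above zero (median 0.57, camera adjusted p = 0.000344). When adjusted over the list alone 5 rose, among them H1f3 (0.70), H2bc4 (0.82) and H2ac4 (0.57). The lists of G1/S and of G2/M lay lower in the same comparison, so this shift alone does not show more S phase. How the labelling kit captures histone transcripts is not known here. Cytosolic ribosomal proteins had 27 of 31 above zero (median 0.16, adjusted p = 0.00837), with 0 passing over the list alone by limma and a value of 0.34 for Rpl27 (0.13 as a mean over its probes). After quantile normalization the median of the list was -0.05, it did not pass, and Rpl27 had a value of 0.11. Markers of thymocytes, another cell type of the thymus, had 11 of 13 above zero (median 0.37, adjusted p = 0.0497), with 3 that rose when adjusted over the list alone, Cd8a (1.17, or 0.70 as a mean over its probes), Cd3e (0.57) and Tcf7 (0.50). The adjusted p with an estimated correlation was 0.745 for histones and thymocyte markers and 0.772 for ribosomal proteins. All β lists are compared on the same arrays, so the shift of the thymocyte markers beside the others is no separate evidence. Histones passed with each array left out in turn, with a median of 0.32 without the treated β replicate 2. Ribosomal proteins did not pass without the treated β replicate 2 (adjusted p = 0.142) or the untreated β replicate 1 (median 0.08, adjusted p = 0.180), and had a median of 0.25 without the untreated β replicate 2. The median of thymocyte markers was 0.22 without the untreated β replicate 1. Thymocyte markers did not pass without the treated β replicate 1 (median 0.06, adjusted p = 0.184), the untreated β replicate 2 (0.229) or either untreated δ array (0.0545 and 0.0536), nor after normexp, quantile normalization or another filter on dim probes (adjusted p between 0.0547 and 0.345), with a median of 0.14 without a filter and 0.17 with probes well above background on all arrays.

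**Figure D3:**
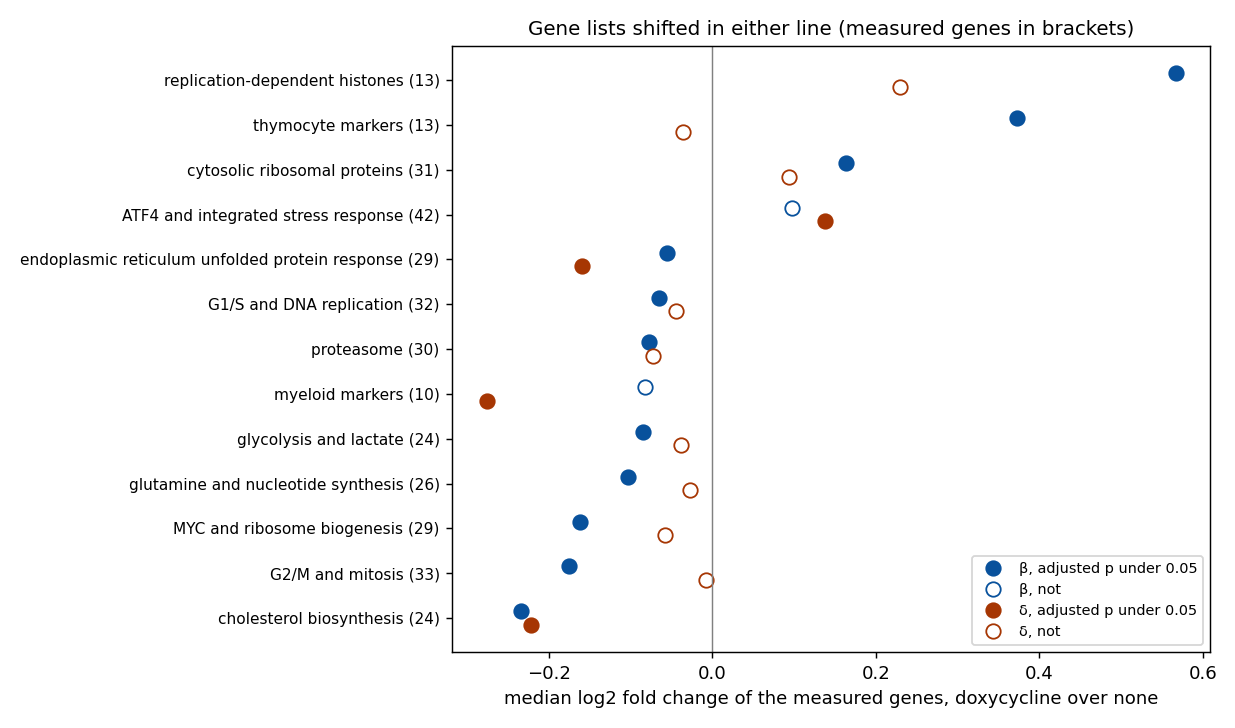
Median log2 fold change with doxycycline of each gene list that passed camera in at least 1 line, for the β line and the δ line. Filled points passed at an adjusted p under 0.05 with the preset correlation, open points did not. Cholesterol biosynthesis lies at -0.23 in the β line and -0.22 in the δ line.

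In the δ line, Ccr7 fell 3.08-fold with doxycycline (-1.62 ± 0.11 SE, n = 2 and 2, limma adjusted p = 0.0351), P2rx7 fell 2.75-fold (-1.46 ± 0.11, adjusted p = 0.0351) and Sbk3 fell 2.40-fold (-1.26 ± 0.11, adjusted p = 0.0408). Bcl2l14, a member of the Bcl-2 family (-1.61), Padi3, a peptidylarginine deiminase (-1.38), the apolipoprotein B receptor gene Apobr (-1.18) and Hrct1 (-1.08) fell too, with adjusted p of 0.0408 or less. Slco1a6, an organic anion transporter, was well above background on both untreated δ arrays and on neither treated array, and fell at least 11.9-fold (adjusted p = 0.000128). Fam228a fell at least 6.05-fold in the same way (adjusted p = 0.0351). The keratin gene Krt20 rose 2.78-fold (1.47 ± 0.13, adjusted p = 0.0408), Ifitm1 rose 2.27-fold (1.18 ± 0.09, adjusted p = 0.0351), and Cyp4b1, not well above background without doxycycline, rose at least 1.27-fold (adjusted p = 0.0408). Of these 12 genes, Slco1a6 alone passed with any β array or any treated δ array left out (adjusted p of the others between 0.0836 and 0.293), in a fit of the 4 arrays compared (0.224) or with a replicate block (0.336). After normexp 8 did not pass, after median centring 6 and after quantile normalization 3, and with an intensity trend Cyp4b1 did not. After normexp the log2 fold changes of Krt20, Bcl2l14, Slco1a6, Fam228a and Cyp4b1 were 0.89, -0.91, -2.11, -1.36 and 0.33. Those of Slco1a6, Fam228a and Cyp4b1 are under their bounds, but the normexp offset shrinks folds against dim groups by construction.

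In all, 14 genes passed in the δ line, 4 higher and 10 lower, and 57 passed without the probes in the patch, 25 higher and 32 lower. The share of higher calls was 28.6%, against 11.1% of 18 after quantile normalization and 0 of 5 after normexp. Leaving out 1 array gave 1 call for any β array, 8 or 15 for the treated δ replicates 1 and 2, 105 without the untreated replicate 1 that holds the patch, and 1684 when that array alone stood for the untreated group.

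In the δ line 4 of 46 lists passed, and none with an estimated correlation (adjusted p = 0.888 for each of the 4). Cholesterol biosynthesis lay lower, with 20 of 24 below zero (median -0.22, camera adjusted p = 0.00117) and 5 that fell when adjusted over the list alone, among them Cyp51 (-0.56), Fdps (-0.75) and Insig1 (-0.49). The unfolded protein response had 23 of 29 below zero (median -0.16, adjusted p = 0.00117) and 2 that fell when adjusted over the list alone, Manf (-0.57) and Sdf2l1 (-0.50), beside a value of -0.43 for Dnajc3. Genes of ATF4 and the integrated stress response had 31 of 42 above zero (median 0.14, adjusted p = 0.0283) and 2 that rose when adjusted over the list alone, the cystine transporter gene Slc7a11 (0.95) and Atf4 itself (0.50), beside a value of 0.42 for Trib3. Myeloid markers, of another cell type, had 8 of 10 below zero (median -0.28, adjusted p = 0.0123), and 3 fell when adjusted over the list alone, Tyrobp (-0.72), Laptm5 (-0.73) and Fcgr3 (-0.48). All δ lists are compared on the same arrays, so the shift of the myeloid markers beside the others is no separate evidence. No member passed over all genes tested. Without the untreated array that holds the patch the medians of cholesterol biosynthesis and of the unfolded protein response were -0.14 and -0.07. When the array with the patch stood alone for the untreated group, cholesterol biosynthesis, ATF4 and the myeloid markers did not pass (adjusted p = 0.0766, 0.577 and 0.117), with a median of 0.08 for ATF4, and without the treated δ replicate 2 the ATF4 list did not (0.113). ATF4 did not pass after median centring or as means over probes either (0.0583 and 0.0943), nor the myeloid markers with probes well above background on all arrays or in a fit of the 4 arrays compared (0.0706 and 0.0677). After normexp the values of Slc7a11, Laptm5 and Fcgr3 were 0.58, -0.41 and -0.12. Lists of the TCA cycle, the nuclear respiratory chain and fatty acid oxidation did not pass in either line, with adjusted p between 0.138 and 0.836.

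**Figure D4:**
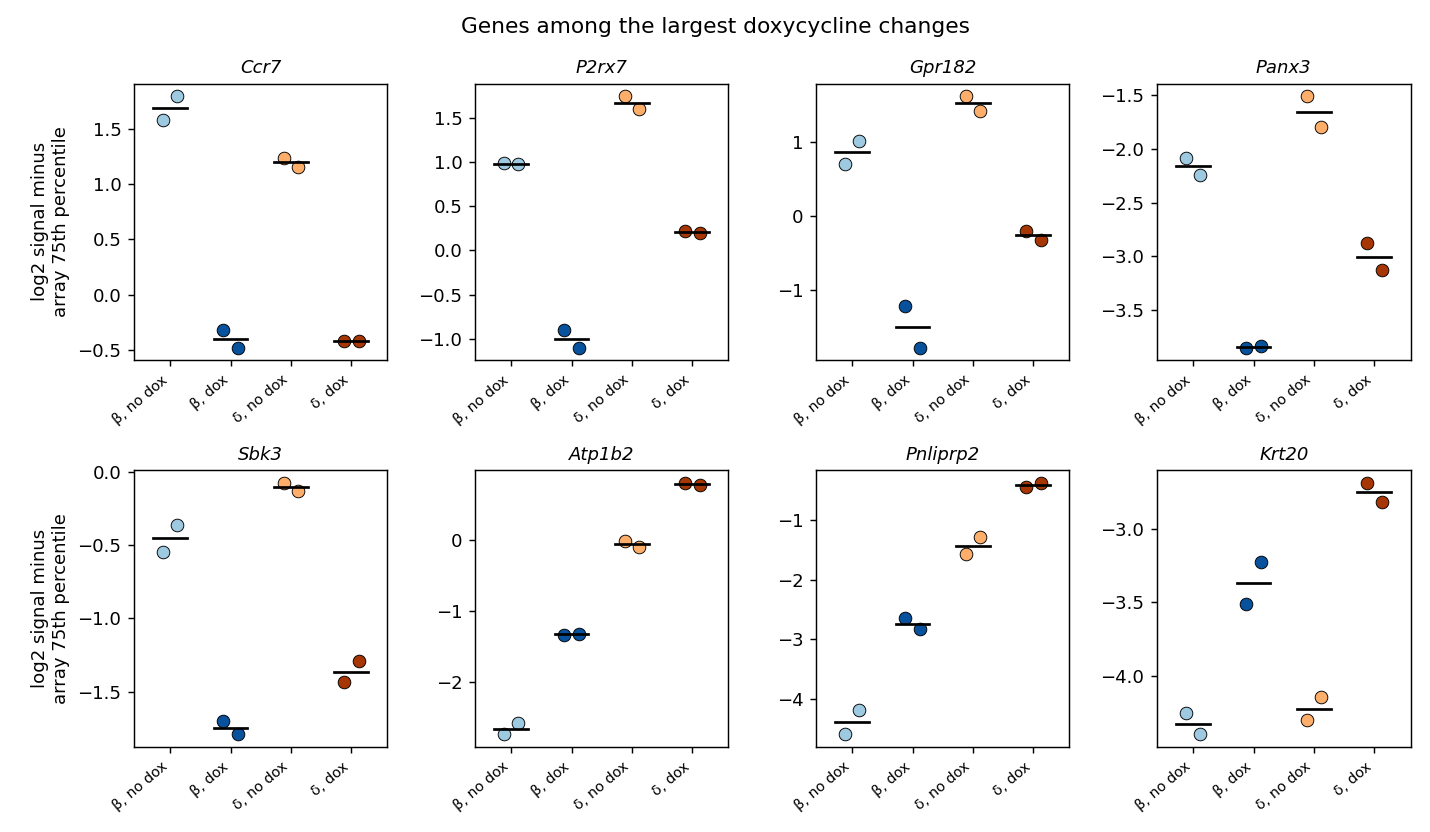
Signal of 8 genes named above on each array, as log2 signal minus the array's 75th percentile, with each group's mean as a line. Every panel has its own vertical range. Ccr7 falls from 1.69 to -0.40 in the β line and from 1.20 to -0.42 in the δ line.

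The mean of both effects was tested as well. A change in 1 line alone can make it pass, so a call does not show that both lines changed. Gpr182 (4.18-fold lower, log2 fold change -2.06 ± 0.15 SE, adjusted p = 0.00927), Ccr7 (-1.85 ± 0.08, adjusted p = 0.00238), P2rx7 (-1.72 ± 0.08, adjusted p = 0.00238), Panx3 (-1.51 ± 0.10, adjusted p = 0.00773) and the homeobox gene Shox2 (-1.33 ± 0.13, adjusted p = 0.0147) fell most, with n = 4 and 4 arrays. Pnliprp2 (1.33), Txndc2 (1.23), Krt20 (1.22), Igdcc4 (1.14) and Fgfbp1 (1.13) rose most, with adjusted p between 0.00927 and 0.0336; spots of Igdcc4 lay in the patch. In all, 593 genes passed, 292 higher and 301 lower, of which 60 changed by at least 2-fold, and 1059 passed without the probes in the patch, 645 higher and 414 lower. Of these 10 genes, Ccr7 and P2rx7 passed with each array left out. The others lost the call without at least 1 array: Txndc2 and Igdcc4 without any β or treated δ array, Fgfbp1 without any of these but the untreated β replicate 2, Pnliprp2 and Shox2 without any treated array, Krt20 without the treated β replicate 2 or a treated δ array, Panx3 without the treated β replicate 2 or δ replicate 1, and Gpr182 without the treated δ replicate 1 (adjusted p between 0.0509 and 0.160). For the counts, leaving out 1 array gave 57, 18, 227 and 391 for the β arrays (treated replicates 1 and 2, then untreated), 9 and 30 for the treated δ arrays, 632 without the array that holds the patch and 2336 without the other untreated δ array. Median centring left 182 calls and normexp 210. None of the 10 genes passed with a replicate block (adjusted p = 0.121 to 0.127), and after normexp Txndc2 did not pass (0.69, adjusted p = 0.0620) and Pnliprp2 and Krt20 had values of 0.88 and 0.80.

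On average over both lines 7 of 46 lists passed camera, and none with an estimated correlation (lowest adjusted p = 0.880). Cholesterol biosynthesis had 21 of 24 genes below zero (median -0.22, adjusted p = 1.45e-05), with 3 that fell over all genes tested, and 10 that fell and 1 that rose when adjusted over the list alone. The unfolded protein response had 22 of 29 below zero (median -0.12, adjusted p = 0.002), with 5 that fell over all genes tested and 7 when adjusted over the list alone. Genes of MYC and ribosome biogenesis (22 of 29 below zero, median -0.10, adjusted p = 0.00436) and of G2/M and mitosis (20 of 33, median -0.11, adjusted p = 0.00751) lay lower too, each with 2 that fell over all genes tested, and 3 and 7 when adjusted over the list alone. Histones had 11 of 13 above zero (median 0.40, adjusted p = 0.002), with 2 that rose over all genes tested and 6 when adjusted over the list alone. Ribosomal proteins had 30 of 31 above zero (median 0.12, adjusted p = 0.00553) and 0 past the limma threshold when adjusted over the list alone. ATF4 and the integrated stress response had 31 of 42 above zero (median 0.10, adjusted p = 0.0327), with 2 that rose over all genes tested, and 7 that rose and 2 that fell when adjusted over the list alone. With an estimated correlation the adjusted p was 0.914 for ribosomal proteins and ATF4 and 0.880 for the others. Cholesterol biosynthesis and the unfolded protein response had passed camera in each line. The MYC, G2/M, histone and ribosomal protein lists had passed in the β line alone, and ATF4 in the δ line alone. How these calls on the average depend on single arrays was not tested.

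Of the 47 calls of the β line and the 14 of the δ line, 6 were shared, 1 higher (Ifitm1) and 5 lower (Ccr7, Hrct1, P2rx7, Padi3 and Sbk3), against 0.00463 and 0.0131 for independent lists of these lengths. The effects share no arrays but come from 1 fit with a common spread per gene, so a gene with a small spread is called more easily in both lines and these numbers do not give what chance alone would yield. Of the β calls, 44 had the same sign in the δ line. Without the patch, 32 of 296 and 57 calls were shared, 12 higher and 20 lower, and 272 of the β calls had the same sign in the δ line. Across all genes, which are not independent replicates, the effects of both lines had a Pearson correlation of 0.218 and a Spearman correlation of 0.316, and 0.313 and 0.328 without the patch. The sign was the same in both lines for 61.2% of genes.

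**Figure D5:**
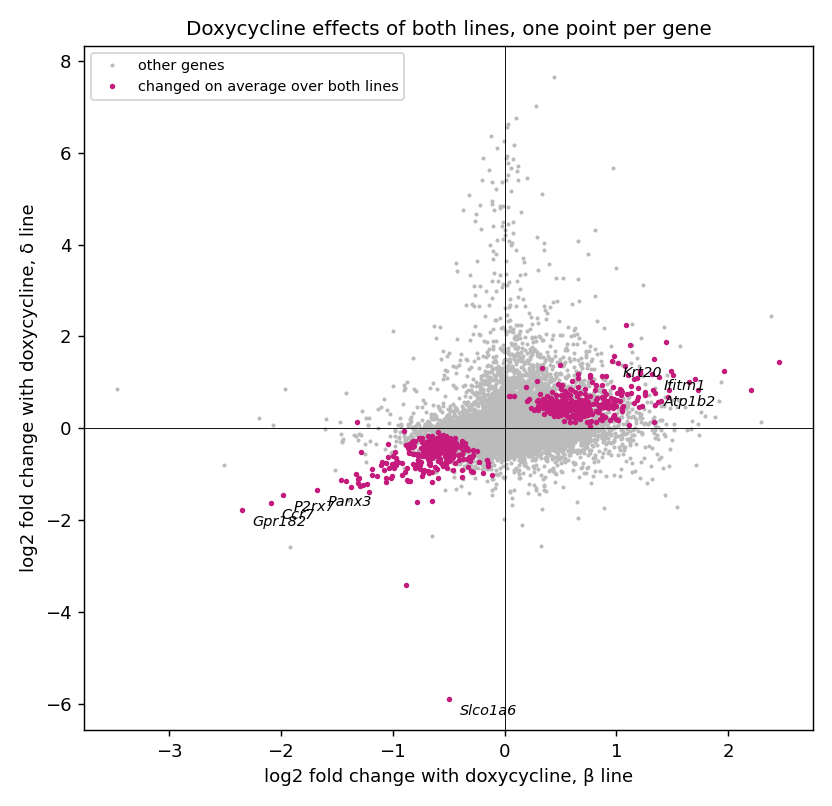
Log2 fold change with doxycycline in the β line (horizontal) and the δ line (vertical), one point per gene, 19023 genes. Coloured points are the 593 genes that changed on average over both lines. Grey points high on the vertical axis include genes whose spots lay in the patch of an untreated δ array.

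Whether the lines responded differently was tested by the difference of their effects. Slco1a6 alone passed in limma, with a fitted log2 difference of -5.40 (adjusted p = 0.00181). It was not well above background on either group of β arrays, so this fitted value is no measure of size. It did not pass after normexp (-2.55, adjusted p = 0.0685), with an intensity trend (0.132) or with a replicate block (0.0541). An unadjusted limma p under 0.05 was reached by 1433 genes, 7.53% of those tested. A share of 0.05 is expected there without any difference. Without the probes in the patch, 1 gene passed the adjusted test as well. Leaving out an array gave 14 or 4 calls for the treated β replicates 1 and 2, 16 or 11 for the untreated ones, 6 or 12 for the treated δ replicates, 64 without the array that holds the patch and 1117 without the other untreated δ array. Among gene lists, G2/M and mitosis shifted upward in the δ line relative to the β line (29 of 33 above zero, median 0.12, adjusted p = 0.0186), as did the mitochondrial ribosome (23 of 33, median 0.15, adjusted p = 0.0301), and thymocyte markers shifted downward (12 of 13 below zero, median -0.31, adjusted p = 0.0323). No member of these lists passed over all genes or when adjusted over the list alone, and each list had an adjusted p = 0.962 with an estimated correlation. None of the 3 passed after quantile normalization or without the untreated β replicate 2, and the mitochondrial ribosome did not pass without the probes in the patch (adjusted p = 0.0802) or without the array that holds it (0.116). Without the untreated β replicate 1 the medians of G2/M and of the mitochondrial ribosome were 0.20 and 0.25, without the untreated β replicate 2 both were 0.05, and after median centring that of G2/M was 0.18. Without the treated β replicate 1 or the treated δ replicate 2, G2/M alone passed, and without the untreated δ replicate 2 the mitochondrial ribosome alone passed. Thymocyte markers did not pass as means over probes or with probes well above background on all arrays (adjusted p = 0.0845 and 0.0550).

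The lines themselves were compared next, without and with doxycycline. Each isoform was carried by 1 line, so these p-values measure the spread between arrays and not between lines. Other differences between these lines cannot be told apart from the isoform. The lines also lay in different columns of the slide, so column and line cannot be told apart either. Without doxycycline, Csf2ra, the α subunit of the GM-CSF receptor, was 46.1-fold higher in the δ line (log2 fold change 5.53 ± 0.10 SE, n = 2 and 2, limma adjusted p = 6e-06), and the kinase gene Stk26 was 65.0-fold higher (6.02 ± 0.19, adjusted p = 3.22e-05). Plxdc2 (4.74), the planar polarity gene Prickle1 (4.03) and Zfp503 (3.83) followed. The tetraspanin gene Tspan8 was 46.4-fold lower in the δ line (-5.54 ± 0.14, adjusted p = 1.54e-05), as were Klra4, a receptor of the Ly49 family (42.5-fold, -5.41 ± 0.10, adjusted p = 6.11e-06), the phosphodiesterase gene Pde3b (-5.15), Clec2f (-4.82) and Dpysl3 (-4.60). Eid2 and Bex4 were not well above background in the β line and at least 135-fold and at least 95.3-fold higher in the δ line, while the potassium channel gene Kcnk1 and Ano9 were at least 39.2-fold and at least 32.3-fold lower there. Under normexp the log2 fold changes of Eid2, Bex4, Kcnk1 and Ano9 were 5.92, 5.28, -4.25 and -3.66, smaller than these bounds. The normexp offset shrinks folds against dim groups by construction, so this does not test the bounds. Gtf2i itself was 1.59-fold higher in the untreated δ line (0.67 ± 0.12, adjusted p = 0.0195), a gene named here after its value was seen, and this difference was past the threshold in neither the fit of the 4 arrays compared (adjusted p = 0.137) nor after median centring (0.0521), nor with the untreated β replicate 1 left out (0.0685), either treated δ array (0.0618 and 0.0588) or the untreated δ replicate 1 (0.0699). In all, 2513 genes passed, 1509 higher and 1004 lower in the δ line, and 2784 without the patch. Leaving out 1 array gave between 1388 and 2150 calls, except 3812 without the untreated δ array that has no patch; a fit of only the 4 arrays compared gave 716.

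Of 46 lists, 20 passed between the untreated lines, and none with an estimated correlation (lowest adjusted p = 0.209). Genes of ATF4 and the integrated stress response were lower in the δ line, with 36 of 42 below zero (median -0.41, adjusted p = 2.45e-08), with 14 lower and 1 higher over all genes tested and 25 and 2 when adjusted over the list alone. Cholesterol biosynthesis was lower as well (21 of 24 below zero, median -0.57, adjusted p = 3.83e-07), with 13 lower over all genes tested and 16 lower and 1 higher when adjusted over the list alone, and so were NF-kappaB and inflammatory genes (23 of 26, median -0.22, adjusted p = 2.52e-06), with 10 lower over all genes tested and 11 when adjusted over the list alone. Their adjusted p with an estimated correlation was 0.555, 0.555 and 0.209. Mesenchymal genes were higher in the δ line (20 of 25 above zero, median 0.27, adjusted p = 0.00288; 0.555 with an estimated correlation), with 7 higher and 1 lower over all genes tested and 8 and 1 when adjusted over the list alone.

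With doxycycline in both lines, the same comparison gave 2903 genes, 1854 higher and 1049 lower in the δ line, and 3443 without the patch. Stk26 (5.49), Csf2ra (5.03), Mdfi (4.82), Arhgap24 (4.55) and Plxdc2 (4.39) were higher, and Tspan8 (-5.83), Klra7 (-5.36), Klra4 (-5.31), Pde3b (-5.02) and Clec2f (-4.82) lower, with adjusted p of 0.00855 or less. Eid2 and Bex4 were at least 187-fold and at least 182-fold higher, and Cdhr1 and Kcnk1 at least 73.4-fold and at least 56.3-fold lower. Spots of Cdhr1 lay in the patch, and it did not pass with any of the 4 treated arrays left out (adjusted p between 0.0680 and 0.0884). Mdfi did not pass without either treated δ array (0.0677 and 0.0629), and its value was 3.82 without the treated β replicate 1 and 5.82 without replicate 2. After normexp the log2 fold change of Arhgap24 was 2.83, and those of Eid2 (5.74), Bex4 (5.58), Kcnk1 (-4.10) and Cdhr1 (-4.24) were smaller than their bounds. Here too the offset shrinks folds against dim groups by construction. The count was 1319 or 1279 without a treated β array and 671 or 787 without a treated δ array. Of 46 lists 16 passed and none with an estimated correlation (lowest adjusted p = 0.435), with ATF4 and the integrated stress response and cholesterol biosynthesis again lower in the δ line. Their medians were -0.35 (adjusted p = 2.56e-07) and -0.51 (adjusted p = 1.64e-05), and each had an adjusted p = 0.605 with an estimated correlation. Of the ATF4 list 12 genes were lower and 1 higher over all genes tested, and 17 and 1 when adjusted over the list alone; of the cholesterol list 14 were lower over all genes tested, and 14 lower and 1 higher when adjusted over the list alone.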

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

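The tests of whether signal was lost locally and of the induced mutant's transcript, and the reading of the ATF4 list, were chosen after the results were seen. Results in which the lines differed in their doxycycline effect were picked out by the test of the difference itself. Slco1a6 differed by -5.40 on the log2 scale (δ minus β, adjusted p = 0.00181), with both β groups not well above background. The median difference was 0.15 for the mitochondrial ribosome, 0.12 for G2/M and mitosis and -0.31 for thymocyte markers, with camera adjusted p of 0.0301, 0.0186 and 0.0323, and none passed with an estimated correlation (adjusted p = 0.962). Outside the gene comparisons, 12 of 17106 probes without a gene name passed for doxycycline on average over both lines, 6 higher and 6 lower. This is a smaller share than the 593 of 19023 named genes. In the single lines, 0 of these probes passed in the β line and 2 in the δ line. Probes in the patch were not left out here. No group has enough arrays for a test of outlying samples.

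The untreated δ arrays disagreed at bright spots. Of the 313 bright spots in even columns that differed by at least 2 on the log2 scale between them, 96.2% lay in tiles found deviant from the odd columns alone, which hold 7.65% of such spots, and 310 were lower on replicate 1. A difference in that sample's RNA would lower the other probes of the same genes as well: for genes with a probe inside the patch that was lower by at least 1 (median -2.71), the 484 probes outside it differed at the median by 0.0764 ± 0.22 (SD). This argues against the RNA and fits a local loss of signal, for which a bubble or a poorly wetted area is a candidate explanation that the files cannot settle.

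A Gtf2i probe that did not represent the gene, A_55_P2040907, was brighter by 1.31 on the log2 scale with doxycycline in the β line. Only 0.197% of 5076 probes of like brightness differed as much, or 0.591% counting the gene's 3 probes, which argues against noise of a dim probe as the whole cause. The transcript of the induced mutant may raise this probe, but the difference of the same probe in the δ line was 0.14, and the position of the probe in the transcript is not known here, so a sequence present in the β mutant alone remains open.

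The doxycycline effects of the lines were correlated, with the same sign for 61.2% of genes. With the line kept as a term, 631 genes passed for the real split of the 8 arrays, against at most 5 for the others. Of 34 splits, the real one alone reached this count, and the split that follows the lines could not be fitted. Many of the others divide the lines unevenly. Every split but the real one also leaves the doxycycline difference in its spread, which can lower its count. This test therefore cannot exclude chance for the average effect. Nothing here shows that the arrays vary independently. A difference between cultures would give the same outcome, and 1 line alone could carry it. The background of dim spots differed between the slide rows (spread of negative controls 12.1 to 14.8 with doxycycline, 21.4 to 28.4 without). Alone it would leave bright genes uncorrelated, but the Spearman correlation was 0.41 among the brightest of 3 equal groups of genes (Pearson 0.19). Calls on average were 123 higher and 65 lower in the dimmest group, 123 and 150 in the middle and 46 and 86 in the brightest. The correlation among bright genes therefore does not settle the role of background in the calls of dim genes. Doxycycline itself, which blocks mitochondrial translation, might act without the induced protein; the ATF4 list, which responds to that block, had an adjusted p of 0.154 in the β line and 0.0283 in the δ line, where it did not pass with an estimated correlation (0.888), without the untreated δ replicate 2 (0.577), after median centring (0.0583) or as means over probes (0.0943), and without a treated line lacking the mutant these cannot be told apart. Other effects of the slide row, and of the uneven detrending, also stay open.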

How the results depend on the processing

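The alternatives that leave out the patch of deviant tiles were chosen after seeing the data; all others were planned. Every alternative kept the direction of the named genes and lists except those given here. With an array left out the β count ranged from 0 to 203, the δ count from 1 to 1684, the average from 9 to 2336, the difference from 4 to 1117, the untreated lines from 1388 to 3812 and the treated lines from 671 to 3225. A group left with a lone array is assumed to vary like the others. Lists ranged from 6 to 14 in the β line, 1 to 5 in the δ line and 0 to 11 for the difference. The Pearson correlation of the effects ranged from 0.117 to 0.270 and the Spearman correlation from 0.172 to 0.401, and Gtf2i from -0.0104 to 0.23 in the β line and from -0.0148 to 0.20 in the δ line. Among β lists, the median of G1/S ranged from -0.165 to 0.03025 and that of the proteasome from -0.191 to 0.0209. Over all alternatives, list shifts kept direction and side of the threshold in 160 cases and lost the call in 35 with the same direction and 3 with the other (β line), against 64, 8 and 0 (δ line).

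Normexp gave 13 calls (β), 5 (δ), 210 (average) and 0 (difference, with 1299 at an unadjusted p under 0.05 in limma), 7 lists in the δ line and 9 for the difference, and correlations of 0.1415 and 0.1995. Quantile normalization gave 0 lists by camera for the difference, 11 of them at an unadjusted p under 0.05, and a median of -0.0497 for ribosomal proteins in the β line. Median centring gave 14, 7 and 182 calls (β, δ, average). Without a filter on dim probes there were 2, 803 and 2209, with 6, 7 and 8 lists (β, δ, difference) and a Pearson correlation of 0.302. Probes well above background on all arrays gave 333, 44 and 950 calls, 0 for the difference (1448 unadjusted), 6 β lists and a Pearson correlation of 0.291. Means over probes gave 31 δ calls, 0.0715 for Hmmr, 0.30 for Dkc1 and, in the β line, 0.52 for Gtf2i (adjusted p = 0.0943). An intensity trend gave 240, 25 and 921 calls and 0 for the difference (1483 unadjusted). With only the 4 arrays compared, which leaves fewer samples to estimate the spread, there were 0 calls in the β line (2934 unadjusted in limma), 1 in the δ line and 716 between the untreated lines. Why the counts differ was not tested for any of these alternatives.

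The slide column as a replicate block gave 0 β calls (3109 unadjusted in limma), 1 δ call, 1 on average and 0 for the difference (1188 unadjusted). Arrays of a column share a place on the slide, and nothing in the labels pairs them otherwise. Their deviations within groups correlated by 0.02 (β) and 0.08 (δ). Leaving out the patch's probes on all arrays gave 296, 57 and 1059 calls and a Pearson correlation of 0.313. Leaving out its spots on that array alone gave 308, 67, 1078 and, for the difference, 5, with a Pearson correlation of 0.293. A slide or scan block was not run because all arrays share both.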

Other observations

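The genes of this part were chosen after their values were seen, while the tests they come from were not. On average over both lines, several inflammatory signals fell with doxycycline in limma: Il6 (-0.92 ± 0.07 SE, adjusted p = 0.00927), Cxcl1 (-0.81 ± 0.07, adjusted p = 0.0115), Ccl7 (-0.88 ± 0.10, adjusted p = 0.0206) and Ccl2 (-0.49 ± 0.08, adjusted p = 0.0384) on the log2 scale. Their list of 26 NF-kappaB and inflammatory genes did not pass camera (median -0.01, adjusted p = 0.314). When adjusted over the list alone 5 fell and 2 rose. Among 8 described targets of TFII-I, Fos rose (0.93 ± 0.10, adjusted p = 0.0147), as did Kdr (0.76 ± 0.07, adjusted p = 0.0115), and the list did not pass (median 0.03, adjusted p = 0.365). Of 25 mesenchymal genes, Snai2 (0.66, adjusted p = 0.0233) and Mmp2 (0.43, adjusted p = 0.0335) rose while Tnc (-0.62, adjusted p = 0.0479) and Loxl1 (-0.47, adjusted p = 0.0344) fell, and that list did not pass either (median 0.14, adjusted p = 0.250). None of these 10 genes passed without either treated δ array (adjusted p between 0.0524 and 0.212), without the treated β replicate 2 (0.0509 to 0.140) or with a replicate block (0.121 to 0.128), and without the treated β replicate 1 Il6 alone passed (0.0464). Ccl2, Snai2, Mmp2, Tnc and Loxl1 did not pass after normexp (0.0586 to 0.192), where Mmp2 and Tnc had values of 0.28 and -0.38, or after median centring (0.0608 to 0.0910). Without the untreated δ replicate 2, the array with the patch stood alone for its group, so calls made there are no sign of robustness. Tnc was among those that did not pass without any other untreated array, and it had a value of -0.09 as a mean over its probes.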
